A study of Mus musculus with 6 samples.

How the data were processed

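The 6 samples are RNA sequencing libraries of mouse CD4+ T cells, enriched as naive cells from spleen with magnetic beads and activated for 24 h with stimulation of CD3 and CD28, per the labels' protocols. The labels place 3 libraries in a control group and 3 in a group with a T cell conditional Satb1 knockout (loxP-flanked Satb1 with Cre under Cd4 regulatory sequences), and groups and replicate numbers were taken from the sample titles. The libraries were made with a commercial RNA-seq kit from total RNA, per the labels' protocols. The kit's strand specificity, read length and sequencer are not given in the sources used here.

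The authors deposited 1 table of raw counts per sample, whole numbers of reads per gene, with no normalization. Reads were aligned with STAR 2.7.3a to mm10 (GRCm38) and counted with HTSeq 0.12.4, per the submitters' processing notes. The annotation release and HTSeq's strand setting are not given in the sources used here, so reads in stretches where genes overlap on opposite strands cannot be assigned with certainty. HTSeq in its usual mode leaves out reads that overlap several genes, and reads with several alignments, which lowers the counts of near-identical genes such as globin copies, MHC class I genes and T cell receptor segments. Each table held 55401 genes and 5 summary lines that name no gene. The summary lines were kept out of library sizes and tests. Reads on no feature made up 9.34 ± 0.159% of all reads in the tables in control and 7.45 ± 0.149% in Satb1 cKO (SD, n = 3), ambiguous reads 5.42 ± 0.015% and 5.55 ± 0.037%, and reads with several alignments 3.05 ± 0.005% and 3.03 ± 0.124%. The 2 remaining lines, for low quality and unaligned reads, held 0%.

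Reads counted on genes ranged from 14895389 to 20266626 per library. Gene symbols, positions and biotypes came from GENCODE M21 (GRCm38), matched on gene identifiers without their version, which placed 55141 of the 55401 genes; positions are 1-based. No pair of libraries held the same values. Within groups, log2 CPM correlated at 0.992 to 0.993 and counts differed by more than sampling noise in every pair (chi-square per degree of freedom of 2.18 to 7.62), so all 6 were kept as separate samples.

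Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes with low counts were removed with filterByExpr, which left 13364 of the 55401 genes, libraries were scaled by TMM, and a quasi-likelihood model with group as its only term was fitted (glmQLFit, glmQLFTest). Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. All adjusted p-values of single genes come from this test unless another tool is named. Standard errors of log2 fold changes were derived from the coefficient and its F statistic. CPM values use TMM-scaled library sizes and are given as mean ± SD over 3 libraries. The biological coefficient of variation was 6.27%.

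In the fit, 34 gene lists were tested, holding 588 different genes, 3 of which had no line in the tables. The lists cover chemokines and their receptors, T helper and regulatory subsets, activation, signalling, cell cycle, metabolism, stress, interferon and cell death genes, markers of other cells that bead enrichment from spleen can leave, and mitochondrially encoded genes. Some genes belong to several lists. Each list was compared with all other genes by camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, with adjustment over the 34 lists. Camera called 23 lists, 17 higher and 6 lower; with the correlation estimated from the data, 0 lists were called, and fry, which tests whether a list's genes move one way on balance, called 29. Counts of members are given over all genes and adjusted over the list alone.

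Named genes were Satb1, the 12 largest rises and 12 largest falls among protein-coding genes that were called, reached a mean of 1 CPM in the higher group and did not overlap between groups, the 5 genes of smallest p in each direction, every tested CC chemokine gene of chromosome 11, and up to 4 called members of smallest p from every other list. The design, the tests, the lists and this rule were fixed in advance of the files. Genes outside the rule are marked as chosen after their values were seen, and not every gene that the rule takes is printed. Single genes that the rule takes and that are withheld are not reported here. Neighbouring genes were compared by counting adjacent tested pairs in which both genes were called, against 1000 shufflings of the calls over the tested genes.

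The analysis was tested on simulated counts drawn from the real means, dispersions and library sizes for the comparison of Satb1 cKO with control, over 13116 genes. At each fold size, 49 or 50 genes were changed. The analysis recovered 69.4% of genes changed 1.5-fold, 68% of those changed 2-fold, 98% of those changed 4-fold and 100% of those changed 8-fold. Of its 174 calls, 7 (4.02%) were false. The real comparison called 5651 genes, so the adjusted p threshold was stricter in the simulation and these shares need not hold for the data. Of 100 lists of unchanged genes, 2 had a camera p under 0.05. The simulated genes were drawn independently of each other, whereas the correlation estimated in the real lists reached 0.911 (MHC class I). The simulated lists therefore do not give the rate of false calls for lists of correlated genes. The simulation and the code were checked only on such data, not on other real samples.

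The alternatives were RLE and upper-quartile scaling, no filter on low counts, a filter of at least 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, a robust dispersion, the replicate number as a block, each library left out in turn, a test against a 1.5-fold change (glmTreat), omission of immunoglobulin, T cell receptor and mitochondrial genes, and, added after the data were seen, omission of the marker genes of other cell types. Permutation tests, exact tests and plots used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.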

Results

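RNA sequencing measured gene transcripts in mouse CD4+ T cells that were enriched as naive cells from spleen with magnetic beads and then stimulated for 24 h through CD3 and CD28. Cells of control mice (3 libraries) were compared with cells of mice in which loxP-flanked Satb1 alleles were exposed to a Cre recombinase driven by Cd4 regulatory sequences, called Satb1 cKO below (3 libraries). The labels do not say whether control mice carried the Cre transgene or were littermates. Effects of Cre or of genetic background therefore cannot be told apart from those of the Satb1 deletion. SATB1 is a nuclear protein that binds AT-rich DNA and takes part in folding chromatin in T lineage cells. The question named by the study's title is how gene expression, in particular that of a chemokine gene cluster, differs in T cells that lack it. Reads counted on genes came to 16871642 ± 2953328 per control library and 17749185 ± 1207370 per Satb1 cKO library (SD, n = 3 each). The labels do not say whether the 3 libraries of a group came from separate mice, so the p-values measure only the spread between these samples, which may be technical.

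Satb1 (ENSMUSG00000023927.15, chromosome 17, 51736187 to 51833290, GRCm38) was lower in each Satb1 cKO library than in each control library. Control libraries held 712, 851 and 727 CPM and Satb1 cKO libraries 426, 546 and 462 CPM, so that the cKO mean was 62.6% of the control mean. The log2 fold change was -0.68 (SE 0.087, adjusted p = 9.7e-05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). These are counts over the whole gene, which can include reads from exons that Cre does not remove, so the remaining level does not measure how complete the deletion was.

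Of 13364 genes tested, 2885 were higher and 2766 lower in Satb1 cKO at an adjusted p under 0.05, together 42.3% of the genes tested. Most of these differences were small: the median absolute log2 fold change of called genes was 0.40, and 700 genes rose and 392 fell by at least 2-fold. A test against a fold change of 1.5 called 611 genes higher and 372 lower. The gene with the smallest p among those that rose was Tigit, an inhibitory receptor of T and NK cells, which went from 7.30 ± 0.501 to 147 ± 9.42 CPM (SD, n = 3; log2 fold change 4.34, SE 0.075, adjusted p = 4.77e-11). Coro2a, a coronin family gene, rose from 16.2 ± 1.21 to 193 ± 12.4 CPM. Pcyt1a, which encodes a rate-limiting enzyme of phosphatidylcholine synthesis, rose from 25.1 ± 1.77 to 226 ± 20.6 CPM. Plscr1, a phospholipid scramblase, and Itgav, the integrin alpha V subunit, rose with log2 fold changes of 1.87 and 2.03 (SE 0.047 and 0.054). The gene with the smallest p among those that fell was Cd4 itself, the co-receptor that marks these cells, which went from 701 ± 20 to 209 ± 4.06 CPM (log2 fold change -1.75, SE 0.038, adjusted p = 2.28e-10).

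Further genes with very small p among those that fell were Ckb, encoding brain-type creatine kinase (log2 fold change -2.58, SE 0.079), and Selenop, encoding the plasma selenium carrier selenoprotein P (-2.17, SE 0.068). Il6ra, encoding the interleukin 6 receptor alpha chain (-1.79, SE 0.060), and Als2cl (-2.63, SE 0.089) were the others. By size of change, the protein-coding genes that fell most included Pdlim4, from 10.1 ± 1.38 to 0.145 ± 0.159 CPM, and Gm14085, from 67.7 ± 4.68 to 2.37 ± 1.28 CPM. Igsf23 fell from 7.26 ± 1.47 to 0.305 ± 0.187 CPM and Tmie from 14.5 ± 1.04 to 1.06 ± 0.348 CPM. Tmie and Als2cl overlap on opposite strands of chromosome 9 (110865711 to 110880113 and 110879870 to 110900530), and reads in the shared stretch cannot be assigned where counting ignores strand. Akr1c18, encoding a steroid-metabolising aldo-keto reductase, was counted in 259 control reads and 2 Satb1 cKO reads, and its relative Akr1c12 in 162 and 13. Galnt9, Fbln1, Arhgap29, Padi3, Dapl1 and Wscd2 complete the 12 largest falls, with log2 fold changes from -3.87 to -3.07. The 12 largest rises included genes of the red cell lineage (the globin genes Hba-a1, Hba-a2, Hbb-bs and Hbb-bt, with Alas2 and Slc4a1), described with the other cell markers. They also included Xcl1, Lhfpl1, Sostdc1 and Cysltr1. Lhfpl1 had 0 control reads and 68 Satb1 cKO reads and was at least 21.4-fold higher, against a floor of 3 reads over the control group, which covers counting error only. Sostdc1 had 2 control reads and 145 Satb1 cKO reads, and Cysltr1, encoding a leukotriene receptor, 1 and 81.

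**Figure D1:**
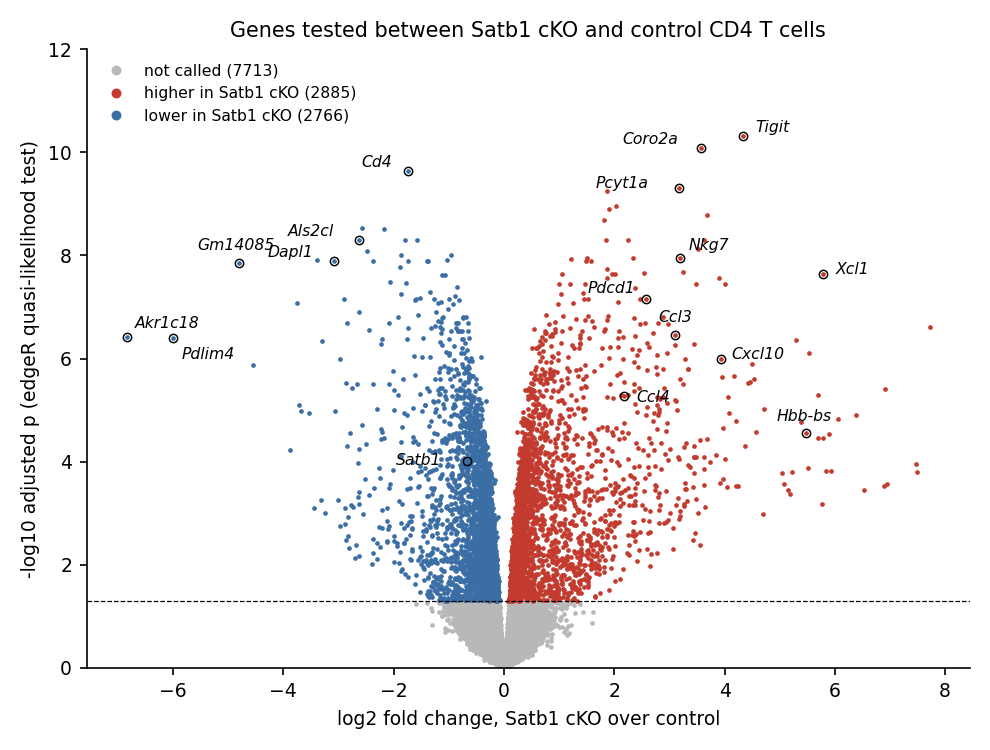
Log2 fold change (Satb1 cKO over control, x axis) against the -log10 adjusted p of edgeR's quasi-likelihood test (y axis) for 13364 genes, with the dashed line at an adjusted p of 0.05. Red points are the 2885 genes higher and blue points the 2766 genes lower in Satb1 cKO; Tigit and Cd4 stand highest on either side, and circles mark genes named in the text.

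The CC chemokine genes of chromosome 11 form the cluster that includes Ccl3, Ccl4 and Ccl5, whose products attract T cells and monocytes. In the Satb1 cKO libraries 5 of 6 tested members rose and 0 fell (5 and 0 adjusted over the list alone). Ccl3 rose from 9.45 ± 3.43 to 83.6 ± 14.3 CPM (SD, n = 3; log2 fold change 3.11, SE 0.189, adjusted p = 3.42e-07), which is 8.61-fold. Ccl4 rose from 37.9 ± 13.7 to 173 ± 25.7 CPM (2.17, SE 0.188, adjusted p = 5.27e-06), and Ccl9 from 1.79 ± 0.781 to 7.2 ± 2.06 CPM (2.01, SE 0.295). Smaller rises were measured for Ccl6, from 1.53 ± 0.36 to 4.04 ± 1.64 CPM (1.41, SE 0.315), and Ccl5, from 3.16 ± 1.31 to 6.40 ± 2.12 CPM (1.05, SE 0.305, adjusted p = 0.0161). Ccl1 stood at 0.787 ± 0.616 and 1.55 ± 0.796 CPM and did not pass the test (adjusted p = 0.162). The other 5 members had too few reads to be tested: Ccl2 had 1 control and 7 Satb1 cKO reads, and Ccl7, Ccl8, Ccl11 and Ccl12 had 0 in every library. The median log2 fold change of the tested members was 1.71, and the list lay above other genes in the camera test (adjusted p = 0.00526), with adjusted p = 0.346 with an estimated correlation. Because the study's title names a chemokine cluster, this list's direction is not independent evidence.

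Ccl5 lost its call when Satb1 cKO replicate 1 was left out (log2 fold change 0.75, adjusted p = 0.0787). Myeloid markers were also higher in these libraries (list median 2.36). Lyz2, encoding lysozyme of monocytes and macrophages, went from 9.23 ± 1.49 to 65.5 ± 26.1 CPM. In Satb1 cKO replicates 1, 2 and 3, Lyz2 stood at 62.3, 41.1 and 93.0 CPM. Ccl9 stood at 7.98, 4.86 and 8.75 CPM, Ccl6 at 5.72, 2.46 and 3.92, and Ccl5 at 8.77, 4.69 and 5.73. Ccl3 (96.1, 68.0 and 86.7 CPM) and Ccl4 (194, 145 and 181) were also lowest in replicate 2, but highest in replicate 1, unlike Lyz2. The lymphocyte genes Xcl1 (20.9, 14.9 and 17.6 CPM) and Nkg7 (26.5, 22.4 and 26.7) were lowest in replicate 2 as well. Cxcr3 was lowest in replicate 1 (6.72, 8.13 and 8.75 CPM). A low level in replicate 2 therefore does not single out myeloid genes. Over 13 of the 14 tested myeloid markers, the ratio of replicate 2 to replicate 1 had a median of 0.641 (0.272 to 1.16). Whether T cells or myeloid cells carried these rises was not tested.

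Neighbouring genes went both ways. In the stretch of chromosome 11 from 81535571 to 84164683, the cluster with its flanks, 27 other genes were tested, of which 6 rose and 4 fell, with a median log2 fold change of 0.019. The 4 that fell were the Schlafen genes Slfn1 (log2 fold change -1.26, SE 0.114), Slfn2 (-0.48, SE 0.050), Slfn3 (-1.08, SE 0.101) and Slfn8 (-0.65, SE 0.122), of a family of closely related sequences linked to T cell quiescence. Slfn5 of the same family rose (0.53, SE 0.183, adjusted p = 0.0373), and Slfn9 and Slfn10-ps did not pass the test. Dusp14, encoding a phosphatase that dampens T cell receptor signalling, rose (2.41, SE 0.229) on the far side of the cluster at 84048041 to 84069261. Between the Schlafen genes and Ccl5, Ap2b1 rose (0.29, SE 0.040, adjusted p = 0.00014), and Taf15, with a log2 fold change of -0.01 (SE 0.038), did not pass the test. The Schlafen genes, Dusp14, Ap2b1 and Taf15 were chosen after their values were seen.

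**Figure D2:**
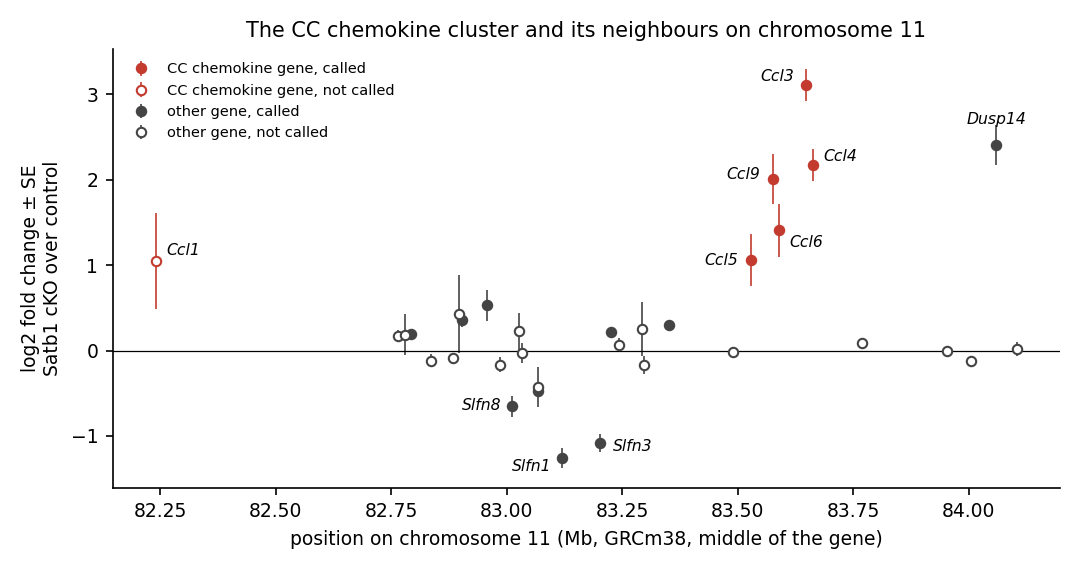
Log2 fold change ± SE (y axis) against the middle of each tested gene on chromosome 11 (x axis, Mb, GRCm38), for the CC chemokine genes (red) and the 27 other tested genes of the stretch (dark grey), filled where the adjusted p is under 0.05. Ccl3 lies highest at 3.11, Ccl1 is the open red point, and the other genes have a median of 0.019.

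**Figure D3:**
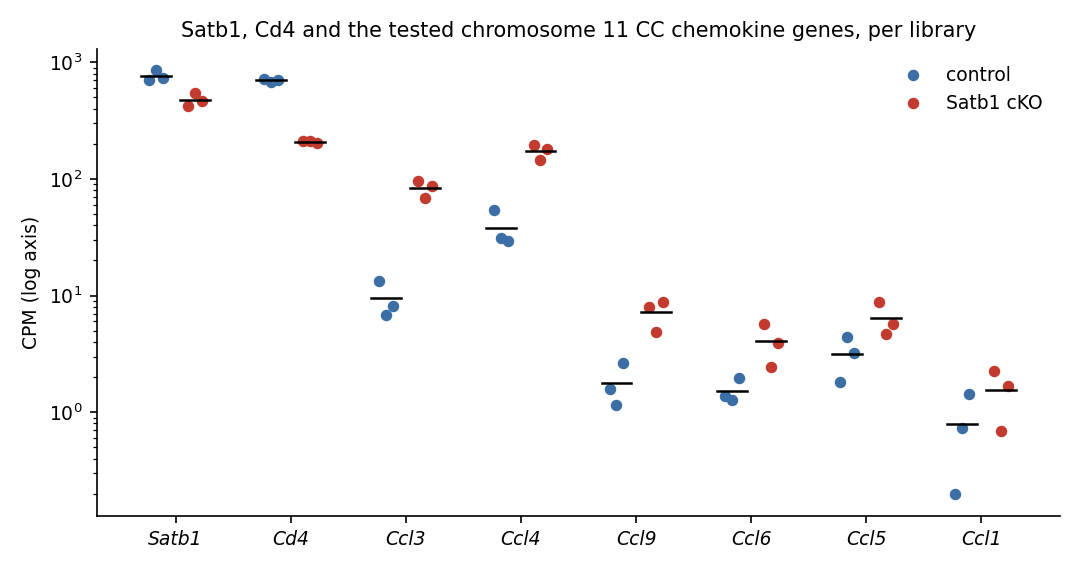
CPM (log axis) of Satb1, Cd4 and the 6 tested CC chemokine genes of chromosome 11 in each control (blue) and Satb1 cKO (red) library, with black lines at the means of 3 libraries. For Ccl3 the control mean is 9.45 and the Satb1 cKO mean 83.6 CPM, and the groups overlap only for Ccl1.

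Chemokines encoded elsewhere and chemokine receptors also differed. Among 10 other tested chemokine genes, 4 rose and 1 fell (4 and 1 adjusted over the list alone): Xcl1, a lymphocyte-derived attractant of dendritic cells, rose from 0.301 ± 0.126 to 17.8 ± 2.96 CPM. Cxcl10 and Cxcl9, interferon-induced ligands of CXCR3, rose with log2 fold changes of 3.94 and 3.44 (SE 0.276 and 0.475). This list did not pass the camera test (adjusted p = 0.135), but did without control replicate 1 (adjusted p = 0.0286) and without a filter on low counts (adjusted p = 0.014). Of 14 chemokine receptor genes, 10 rose and 1 fell (11 and 2 adjusted over the list alone; camera adjusted p = 0.00144, and adjusted p = 0.273 with an estimated correlation). The rises included Cxcr3 (log2 fold change 2.88, SE 0.252), Ccr9 (2.81, SE 0.269), Cxcr4 (1.76, SE 0.127) and Ccr4 (1.31, SE 0.116), receptors by which T cells home to inflamed tissue, gut, marrow and skin. Adhesion and homing genes went both ways, with 9 of 20 higher and 7 lower (9 and 7 adjusted over the list alone; camera adjusted p = 0.33). Itgae, the integrin of tissue-resident T cells, rose from 1.35 ± 0.124 to 8.83 ± 0.451 CPM and Icam1 rose by a log2 fold change of 1.38 (SE 0.089), while Itga6 fell (-1.77, SE 0.079). In these libraries the myeloid and dendritic cell marker lists were higher in Satb1 cKO as well (medians 2.36 and 0.67).

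Of 15 tested Th1 genes, 13 rose and 1 fell (13 and 1 adjusted over the list alone; camera adjusted p = 0.000176, and adjusted p = 0.372 with an estimated correlation). Runx3, a transcription factor of cytotoxic and Th1 cells, rose from 71.1 ± 3.58 to 141 ± 4.62 CPM. Ifngr1 rose with a log2 fold change of 1.48 (SE 0.115), and the kinase gene Txk fell (-1.12, SE 0.093). Ifng, the Th1 cytokine gene, named after its values were seen, went from 0.971 ± 0.817 to 10.4 ± 3.78 CPM. Of 19 regulatory T cell genes, 14 rose and 4 fell (14 and 4 adjusted over the list alone; camera adjusted p = 0.00133, and adjusted p = 0.364 with an estimated correlation). Ikzf2, encoding Helios, rose (1.59, SE 0.062), as did Nt5e, encoding the ectoenzyme CD73 (1.87, SE 0.081). Tnfrsf4, encoding OX40, fell from 394 ± 24.0 to 132 ± 5.82 CPM and Gpr83 fell with a log2 fold change of -2.44 (SE 0.143). Foxp3, the defining transcription factor of these cells, also named after its values were seen, went from 22.2 ± 4.61 to 61.6 ± 6.64 CPM. In the same libraries the list medians of myeloid, NK cell and gamma-delta T and NKT cell markers were 2.36, 1.29 and 1.18 (NK cell markers not called).

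The Th2, Th17 and Tfh lists did not pass the camera test with all libraries (adjusted p = 0.452, 0.11 and 0.631). The Th17 list was called higher when control replicate 1, 2 or 3 was left out (adjusted p = 0.0383, 0.024 and 0.0269). Of 12 tested Th2 genes, 4 rose and 2 fell (4 and 3 adjusted over the list alone), among them Maf (log2 fold change 2.59, SE 0.165) and Nfil3 (1.65, SE 0.186). Of 10 Th17 genes, 7 rose and 2 fell (7 and 2 adjusted over the list alone): Il21 rose (2.72, SE 0.262), while the interleukin 6 receptor genes Il6ra and Il6st fell (-1.79 and -1.03). Of 15 Tfh genes, 8 rose and 7 fell (8 and 7 adjusted over the list alone), with Sh2d1a higher (1.26, SE 0.063) and Slamf6 lower (-1.02, SE 0.053).

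Inhibitory receptor and exhaustion genes rose in 12 of 17 tested members and fell in 3 (12 and 4 adjusted over the list alone; camera adjusted p = 0.00299, and adjusted p = 0.309 with an estimated correlation). Besides Tigit, Pdcd1, encoding PD-1, rose from 51.2 ± 12.1 to 307 ± 21.9 CPM. Tox, a transcription factor of exhausted T cells, rose with a log2 fold change of 1.45 (SE 0.071), whereas Ctla4 fell (-0.76, SE 0.048). Among activation and immediate early genes, 15 of 26 rose and 7 fell (15 and 8 adjusted over the list alone; camera adjusted p = 0.0305, and adjusted p = 0.472 with an estimated correlation), with Tnfrsf9 (1.01, SE 0.045), Egr2 (0.92, SE 0.054) and Il2ra (0.76, SE 0.046) higher. Tnfrsf4, the member of smallest p on this list, fell (-1.57, SE 0.053). Of 20 TNF and NF-kB genes, 14 rose and 2 fell (14 and 2 adjusted over the list alone; camera adjusted p = 0.000981, and adjusted p = 0.371 with an estimated correlation), including Cd83 (2.34, SE 0.088), Tnfrsf1b (1.19, SE 0.053) and Nfkb2 (0.75, SE 0.045). Markers of B cells had a median log2 fold change of 0.95 in these libraries.

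Cd4 and Zbtb7b fell, and most tested CD8 lineage genes rose. Alongside the fall of Cd4, Zbtb7b, encoding the CD4 lineage factor ThPOK, fell from 146 ± 4.81 to 62.2 ± 6.03 CPM. Of the CD8 lineage genes, 7 of 9 tested members rose with 0 lower (7 and 0 adjusted over the list alone; camera adjusted p = 8.65e-05, and adjusted p = 0.273 with an estimated correlation). Cd8a rose from 0.792 ± 0.243 to 6.28 ± 1.39 CPM, a level that stayed far below that of Cd4. Cd8b1, named after its values were seen, was at 18.1 ± 1.98 and 19.8 ± 2.19 CPM and did not pass the test (adjusted p = 0.373). Cytotoxic granule and killer cell genes rose in 11 of 14 members and fell in 0 (11 and 0 adjusted over the list alone; camera adjusted p = 3.98e-05, and adjusted p = 0.273 with an estimated correlation). Nkg7 stood at 2.75 ± 0.040 and 25.2 ± 2.41 CPM, Crtam at 2.47 ± 0.860 and 19.5 ± 2.65 CPM and Serpinb9 at 43.7 ± 8.34 and 158 ± 7.34 CPM. NK cell markers (4 tested, 3 higher and 0 lower, 3 and 0 adjusted over the list alone) did not pass the camera test (adjusted p = 0.0515). Gamma-delta T and NKT cell markers did (6 tested, 4 higher and 0 lower, 4 and 0 adjusted over the list alone; adjusted p = 0.0136, and adjusted p = 0.372 with an estimated correlation). Tcrg-C2 (log2 fold change 1.94, SE 0.247) and Trdc (1.09, SE 0.182) were among them. Without immunoglobulin, T cell receptor and mitochondrial genes the latter list kept fewer members and lost its call (adjusted p = 0.672).

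Genes of T cell receptor signalling fell in 13 of 25 tested members and rose in 3 (14 and 3 adjusted over the list alone; camera adjusted p = 0.000373, and adjusted p = 0.289 with an estimated correlation). Ptprc, encoding the phosphatase CD45, fell from 2330 ± 47.9 to 1292 ± 69.4 CPM. Prkcq, encoding protein kinase C theta, fell from 249 ± 20.2 to 115 ± 4.45 CPM and the co-stimulatory receptor gene Cd28 from 610 ± 28.0 to 341 ± 16.7 CPM. Thymic and chromatin regulators fell in 13 of 28 members and rose in 4 (14 and 4 adjusted over the list alone; camera adjusted p = 0.0054, and adjusted p = 0.346 with an estimated correlation), with Ikzf1, encoding Ikaros, at 660 ± 10.4 and 337 ± 7.65 CPM. Naive and quiescence genes fell in 14 of 22 members and rose in 1 (14 and 1 adjusted over the list alone; camera adjusted p = 0.00018, and adjusted p = 0.325 with an estimated correlation). Dapl1 fell from 28.3 ± 0.983 to 3.32 ± 0.598 CPM, Als2cl from 198 ± 19.7 to 31.9 ± 3.62 CPM. Lef1 and Bach2, transcription factors of naive T cells, fell with log2 fold changes of -0.99 and -0.65 (SE 0.048 and 0.039). Red cell transcripts differed in the opposite direction in the same libraries (list median 5.49). In Satb1 cKO, Hbb-bs and Hba-a1 stood at 691 ± 463 and 356 ± 221 CPM. Globin reads at these levels are too small a part of all counts to bring about the falls given here.

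Cell cycle genes fell in 22 of 30 tested members and rose in 1 (22 and 1 adjusted over the list alone; camera adjusted p = 1.6e-06, and adjusted p = 0.364 with an estimated correlation), with a median log2 fold change of -0.39, among them Top2a (-0.80, SE 0.066) and the replication genes Pcna (-0.44, SE 0.037) and Mcm4 (-0.42, SE 0.039). Glycolysis genes fell in 14 of 21 members and rose in 2 (16 and 2 adjusted over the list alone; camera adjusted p = 0.000176, and adjusted p = 0.372 with an estimated correlation), including the lactate exporter gene Slc16a3 (-1.92, SE 0.166), Pdk1 (-1.15, SE 0.073) and Ldha (-0.33, SE 0.029). Cholesterol synthesis genes fell in 13 of 23 members and rose in 1 (13 and 1 adjusted over the list alone; camera adjusted p = 0.00367, and adjusted p = 0.289 with an estimated correlation), with Dhcr7 at -0.64 (SE 0.060). Genes of the unfolded protein response and amino acid stress rose in 12 of 20 members with 0 lower (13 and 0 adjusted over the list alone; camera adjusted p = 2e-04, and adjusted p = 0.289 with an estimated correlation), among them the chaperone gene Hspa5 (0.41, SE 0.034). Heat shock genes rose in 10 of 13 members with 0 lower (11 and 0 adjusted over the list alone; camera adjusted p = 0.000205, and adjusted p = 0.273 with an estimated correlation), with Hspa1b at 1.54 (SE 0.176). Measures of library composition also differed: reads on no annotated feature made up 9.34 ± 0.159% of control and 7.45 ± 0.149% of Satb1 cKO reads, and mitochondrially encoded genes 1.55 ± 0.030% and 1.30 ± 0.098% of counted reads. In both, all control libraries lay above all Satb1 cKO libraries (two-sided exact permutation p = 0.1, the smallest that 3 against 3 libraries allow; adjusted p = 0.14 over 7 library measures). Of 13 mitochondrially encoded genes, 7 fell and 0 rose (7 lower and 1 higher adjusted over the list alone; camera adjusted p = 0.192), for example mt-Nd5 (-0.56, SE 0.057).

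The interferon gene lists did not pass the camera test with all libraries. Without control replicate 1 the type I interferon list was called lower (adjusted p = 0.00032), and without control replicate 2 or 3 the interferon gamma list was called higher (adjusted p = 0.0269 each). Type I interferon response genes fell in 10 of 34 tested members and rose in 4 (10 and 4 adjusted over the list alone; camera adjusted p = 0.153): Ifi214 fell from 9.73 ± 1.41 to 1.86 ± 0.395 CPM and Phf11b from 37.5 ± 7.16 to 10.5 ± 1.52 CPM. Bst2 rose (log2 fold change 0.68, SE 0.054). Interferon gamma response genes rose in 6 of 25 members and fell in 0 (5 and 0 adjusted over the list alone; camera adjusted p = 0.149), with Socs1, a feedback inhibitor of cytokine signalling, at 62.4 ± 14.8 and 137 ± 9 CPM. MHC class I genes rose in 9 of 15 members and fell in 1 (9 and 1 adjusted over the list alone; camera adjusted p = 0.00595, and adjusted p = 0.543 with an estimated correlation). H2-K1 and H2-D1 rose with log2 fold changes of 0.50 and 0.58 (SE 0.056 and 0.055) and H2-Q6 from 88.0 ± 12.9 to 355 ± 7.02 CPM; these genes are near-identical in sequence, so how reads were split between them is uncertain. Apoptosis genes went both ways, with 6 of 20 higher and 6 lower (6 and 6 adjusted over the list alone), a median log2 fold change of -0.01, a mean of 0.002 and no call (camera adjusted p = 0.91). Bcl2l11, encoding the death-promoting protein BIM, fell (-1.27, SE 0.062) and Pmaip1, encoding NOXA, rose (1.19, SE 0.124). Of 16 JAK-STAT feedback genes, 8 rose and 3 fell (8 and 3 adjusted over the list alone; camera adjusted p = 0.176), with Cish at 0.85 (SE 0.060). Dendritic cell and B cell markers were higher in the same Satb1 cKO libraries (medians 0.67 and 0.95).

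Markers of cells other than CD4+ T cells were higher in Satb1 cKO. All 8 tested erythroid and platelet markers rose (8 adjusted over the list alone; camera adjusted p = 0.000205, and adjusted p = 0.364 with an estimated correlation). Hbb-bs, an adult beta globin gene, stood at 15.7 ± 1.99 CPM in control and at 162, 1023 and 887 CPM in the Satb1 cKO libraries, and Hba-a1 at 8.62 ± 1.35 and 356 ± 221 CPM. The globin copies are near-identical, and how reads were divided between them is uncertain. Slc4a1, Hbb-bt and Alas2 lost their calls with limma-voom (adjusted p = 0.1, 0.0786 and 0.0622). Of 14 monocyte, macrophage and neutrophil markers, 13 rose and 0 fell (13 and 0 adjusted over the list alone; camera adjusted p = 8.02e-05, and adjusted p = 0.346 with an estimated correlation), including S100a9 (0.482 ± 0.262 and 7.36 ± 3.16 CPM) and Mpeg1 (4.35 ± 1.24 and 27.1 ± 13.5 CPM). Of 13 B cell markers, 7 rose and 0 fell (8 and 0 adjusted over the list alone; camera adjusted p = 0.0054, and adjusted p = 0.372 with an estimated correlation), with Cd79b at 0.473 ± 0.160 and 3.97 ± 0.286 CPM and Igkc at 1.99 ± 1.5 and 25.5 ± 10.1 CPM. Of 8 dendritic cell markers, 5 rose and 0 fell (5 and 1 adjusted over the list alone; camera adjusted p = 0.0304, and adjusted p = 0.346 with an estimated correlation), among them Zbtb46 (log2 fold change 2.36, SE 0.129). This list lost its call without Satb1 cKO replicate 1 (adjusted p = 0.102). With all marker genes of other cell types left out, an alternative chosen after seeing the data, 2806 genes were higher and 2826 lower. This removes only the marker genes and leaves any reads that other cells add to the remaining genes. It therefore cannot show how far other cells account for the calls.

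**Figure D4:**
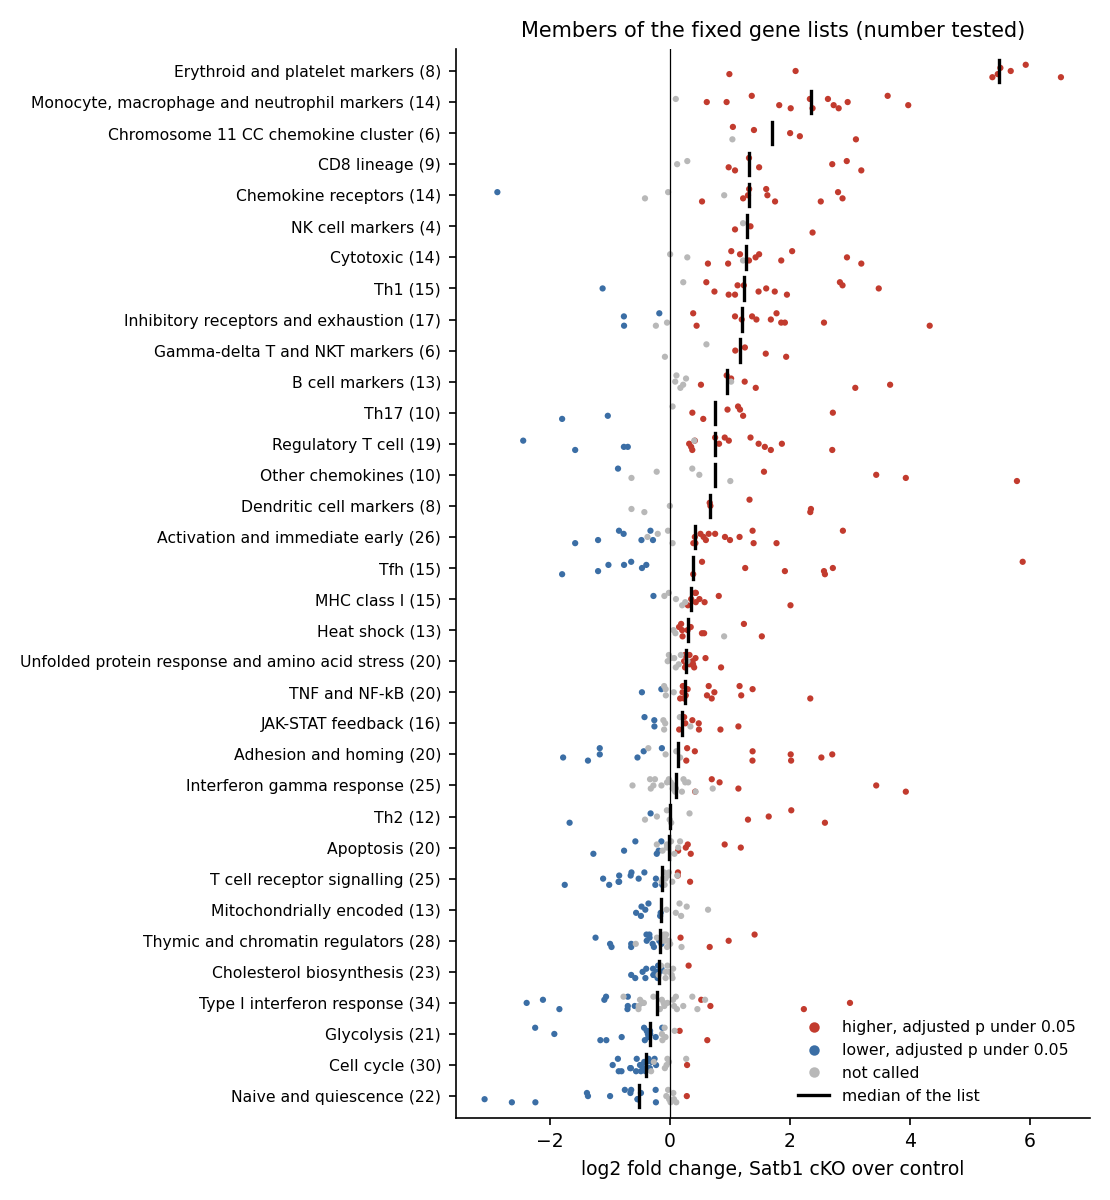
Log2 fold change (Satb1 cKO over control, x axis) of each tested member of the 34 gene lists (y axis, number tested in parentheses); points are red where higher, blue where lower and grey where not called, and black lines mark list medians. Medians run from 5.49 for erythroid and platelet markers to -0.51 for naive and quiescence genes.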

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

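The permutation tests in this part were chosen after the shares were seen. Reads that HTSeq counts as ambiguous, since they overlap several genes, are outside the comparisons made above, and their share was higher in every Satb1 cKO library than in every control library. They made up 5.55 ± 0.037% of Satb1 cKO reads (lowest 5.51, highest 5.57) and 5.42 ± 0.015% of control reads (lowest 5.40, highest 5.43; SD, n = 3; two-sided exact permutation p = 0.1, the smallest that 3 against 3 libraries allow). Control replicate 1 lay at 23.06 on the 2nd principal component (7.91% of variance), and control replicates 2 and 3 at -10.58 and -12.62. Counts of control replicate 1 differed from those of replicates 2 and 3 with a chi-square per degree of freedom of 7.62 and 6.70, against 2.18 between replicates 2 and 3. Groups of 3 libraries are too small to test single libraries for standing apart.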

How the results depend on the processing

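All alternatives but the omission of marker genes of other cells were chosen before the data were examined. That omission takes out only the marker genes, so it does not test whether other cells raised the remaining genes. The numbers of genes called stayed within 1.5 times of those reported, 2885 higher and 2766 lower, under 16 of 17 alternatives each, and no gene called in both changed direction under any of them. Against a fold change of 1.5, 611 genes were higher and 372 lower, fewer by that test's construction. Without single libraries the counts ranged from 2396 to 2898 higher and from 2275 to 2937 lower. DESeq2 called 2522 and 2392 genes, and 4902 of its 4914 calls were also made by edgeR. Satb1 kept its call in all 16 alternatives, with log2 fold changes from -0.79 to -0.60 without single libraries. The chromosome 11 CC chemokine list kept its direction and its camera call in 16 alternatives, 3 of which (DESeq2, limma-voom and the robust dispersion) change the gene test and leave the list test's input as it was, with medians from 1.49 to 1.94 without single libraries; with an estimated correlation its adjusted p was 0.346, and under fry 0.00312. The share of called neighbours with the same direction was past the shuffled values in all 16 alternatives, 59.6 to 63.4% without single libraries.

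Replicate numbers did not pair the libraries: same-numbered libraries deviated from their group means with correlations of 0.021, -0.013 and 0.028, and not every library correlated best with its own number. With the replicate number as a block, 2861 genes were higher and 2702 lower, 5375 of them called without it, and the dendritic cell list had an adjusted p of 0.0506. Among the other 33 lists, 4 results reversed direction, none of them called: interferon gamma response (adjusted p = 0.428) and apoptosis (0.981) without control replicate 1, apoptosis (0.973) without Satb1 cKO replicate 1, and Th17 under fry (0.676). Without single libraries adjusted p ranged from 0.0269 to 0.428 for interferon gamma response, which was called without control replicate 2 or 3, and from 0.662 to 0.981 for apoptosis. Fry called 6 of the 33 lists that camera had not, among them apoptosis, which it called lower (adjusted p = 0.0105). The type I interferon list ranged from 0.00032, without control replicate 1, to 0.495, and Th17 from 0.024 to 0.259. The cause was not tested. An estimated correlation ended the calls of 22 of these lists. Lists near the threshold moved across it: NK cell markers were called in 9 of 17 alternatives, with the lowest adjusted p of 0.00521 without Satb1 cKO replicate 2. Among the genes printed here, these changed their call: Slc4a1, Hbb-bt and Alas2 with limma-voom, Gbp3 with a robust dispersion (0.112), Ccl5 without Satb1 cKO replicate 1, Fcgr3 without Satb1 cKO replicate 3 (0.0507), Tcf4 without control replicate 1 or Satb1 cKO replicates 1 or 2 (0.0603 to 0.0852), and Ccl1, which passed without a filter on low counts (0.019). At this depth and with 3 libraries per group, 68 to 69.4% of simulated genes changed by 1.5-fold or 2-fold were recovered. Far fewer genes were changed in the simulation than were called in the data, so this share does not measure recovery in the data. A gene that is not called may still differ by that much.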

Other observations

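Genes in this part were chosen after their values were seen, and so were its tests, except the test of neighbouring genes and the fixed gene lists. Of 10 immunoglobulin and plasma cell genes picked in this way, with no list test, 8 were called higher and Ighm and Ighd were not called. Ighg1 went from 0.158 ± 0.096 to 7.63 ± 2.05 CPM (SD, n = 3), Ighg2b from 0.217 ± 0.228 to 11.6 ± 4.52 CPM and Jchain, encoding the joining chain of secreted antibodies, from 0.750 ± 0.713 to 8.15 ± 1.98 CPM (adjusted p = 5.01e-05), while Ighm, at 248 ± 29.5 and 268 ± 33.6 CPM, did not pass the test (adjusted p = 0.362).

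Called genes lay next to each other more often with the same sign than shuffled calls did. Adjacent pairs included overlapping genes, which can share reads where counting ignores strand. Shuffling breaks that link, so the excess cannot be assigned to position alone. Among 13320 adjacent pairs, both genes were called in 18.7%, against 17.9% in shuffled data, and 60.2% of those pairs moved in the same direction, against 50% (highest of 1000 shufflings 53.4%; permutation p = 0.000999, the smallest they can give). On chromosome 11 from 54054928 to 54699285, 6 neighbouring genes all fell: Pdlim4 (log2 fold change -5.996, SE 0.373), P4ha2 (-2.78, SE 0.474), the cytokine gene Il3 (-1.67, SE 0.333), Acsl6 (-1.65, SE 0.189), Fnip1 (-0.81, SE 0.088) and Rapgef6 (-0.75, SE 0.055). Irf1, at 53770014 to 53778374, did not pass the test (0.05, SE 0.160). Between Irf1 and Pdlim4, Slc22a5 (53864542 to 53891660) rose (0.363, SE 0.092, adjusted p = 0.00787). On chromosome 18, genes beside the interferon-induced GTPase gene Iigp1 (0.70, SE 0.224) rose: Gm4951 (2.28, SE 0.320), Gm4841 (2.90, SE 0.557), AC151990.1 (4.46, SE 0.356) and Smim3 (3.48, SE 0.157), the last at 60474191 to 60501987. In control they were low, at 1.38, 0.398, 0.253 and 2.15 CPM in this order. Gm5970 is annotated within the span of Gm4951, so their reads may not be told apart. On the X chromosome, Mid1 (169685199 to 170005736) fell from 9.96 to 2.12 CPM, and 3 genes annotated within its span fell with log2 fold changes from -2.64 to -2.45, whose reads cannot be told from those of Mid1 where counting ignores strand.

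The T cell receptor alpha V segments on chromosome 14 changed by position. Of 59 tested Trav segments, 8 rose and 19 fell. Among the 20 farthest from the constant gene (52427928 to 53122610), 11 fell and 0 rose, with a median log2 fold change of -1.10, and among the 19 nearest to it (53598828 to 53876752), 8 rose and 0 fell, with a median of 0.45. Across segments, which are not independent replicates, position and log2 fold change correlated with Pearson's r = 0.719 and Spearman's rho = 0.833 (permutation p = 1e-05 for each, the smallest that 100000 resamples give; 1.25e-05 after adjustment over 5 sets), and r was 0.686 without the 2 segments farthest from the median position. Of the 19 tested Trbv segments of the beta locus, 9 fell and 0 rose, with a median log2 fold change of -0.28. Their position and log2 fold change had rho = -0.333 (permutation p = 0.162).

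A strain haplotype with other copies of the duplicated segments was predicted to leave no trend past the last duplicated segment, yet rho was 0.892 over the 34 segments there. Duplicated segments were told only by a d or n in their names, and related segments without that letter can remain among the 34. The trend there therefore cannot exclude such a haplotype. Gamma-delta T cells that carry segments shared with the delta chain would leave none without those segments, where rho was 0.79. Less alpha chain message as a whole would raise no segment, and 8 rose. This does not exclude a fall of receptor message alongside the trend. Constant genes of all T cell receptor chains together held 0.060 ± 0.002% of counted reads in Satb1 cKO and 0.074 ± 0.002% in control. A candidate explanation, as a hypothesis, is that Satb1 cKO thymocytes made fewer successive alpha chain rearrangements, which start with V segments near the J segments and 5' J segments: the 5' J segments (Traj31 and above) held 22.03 ± 2.03% of Traj reads in Satb1 cKO and 12.6 ± 0.52% in control, a difference of 9.48 percentage points with no overlap (two-sided exact permutation p = 0.1, the smallest 3 against 3 libraries allow; adjusted p = 0.14 over 7 library measures). Reads that span segments are left out of such counts, and a different selection of T cells in Satb1 cKO mice was not tested.

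The higher markers of other cells were weighed next. If fewer T cells alone were the cause, with the other cells in unchanged proportion, markers that T cells do not transcribe would rise alike. Among the 6 tested red cell genes of the fixed list, the lowest log2 fold change was 5.38. It exceeded the highest of the 13 tested B cell markers by 1.70. Which B cell markers the T cells transcribe was not tested, and Ighm of that list stood at 248 ± 29.5 CPM in control. Some immunoglobulin genes that are not on the B cell list rose as much as red cell genes: Ighg1 (5.53, SE 0.375), Ighg2b (5.69, SE 0.491), Ighg2c (5.78, SE 0.642) and Igha (6.39, SE 0.623). Ighg3 (3.43), Jchain (3.46) and Sdc1 (1.34) rose less. The size of the gap therefore depends on which genes are on the B cell list. Red cell precursors may have been left in the Satb1 cKO libraries in different amounts: the erythroid genes were 5.81 times as high in replicate 2 as in replicate 1 (median of 6 genes, 3.94 to 8.45), whereas 13 of the 14 tested myeloid markers had a median ratio of 0.641. Whether such cells are more frequent in the spleens of Satb1 cKO mice or were removed less well, and whether T cells themselves transcribe any of these genes, stays open and was not tested.

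The rise of Ccl3 and Ccl4, a gain of 209 CPM together, was set against what other cells would bring. The gain was 19.3 times that of S100a8 and S100a9, abundant in neutrophils, and 1.62 times that of 20 monocyte, macrophage and neutrophil markers together (111 ± 8.42 and 241 ± 61.2 CPM). It was 70.7 times that of 11 NK cell genes (3.35 ± 0.801 and 6.32 ± 3.07 CPM), Gzma and the NK cell markers that stand on no other list, which leaves out Eomes and Tyrobp, and 0.528 times that of 34 NK cell and cytotoxic genes together, many of which T cells also express. Neutrophils, NK cells and monocytes or macrophages cannot be told apart from T cells as a source, because no table here gives the level of Ccl3 and Ccl4 in activated cells of these types. Transcription of Ccl3 and Ccl4 by the T cells of Satb1 cKO mice stays open as a hypothesis that these bulk counts did not test.

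Of the 10 splits of the 6 libraries into 3 and 3, 1, the real one, gave as many as 5651 called genes, and the highest of the others gave 0. With 10 splits a share under 0.05 cannot be reached. Every other split mixes control and Satb1 cKO libraries, so the group difference adds to its spread within groups and few calls would follow in any case. The contrast with 0 is therefore no separate evidence.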
